A study of Mus musculus with 12 samples.

How the data were processed

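Total RNA of mouse fat cell lines was measured on 12 Affymetrix expression arrays, 3 for each of 4 groups: 3T3-L1 preadipocytes, 3T3-L1 adipocytes, brown preadipocytes and brown adipocytes. Per the labels' protocols, RNA was purified with a kit for lipid-rich tissue, its integrity was read on a Bioanalyzer, and it was amplified into biotin-labelled cRNA for arrays that probe the 3' ends of transcripts. The deposited values were linear signal intensities, 1 per probe set and array, made with Affymetrix Expression Console per the submitters' processing notes. The version and the summarisation algorithm are not given in the sources used here. In the values themselves, the mean signal after trimming 2% at each end lay between 500.003 and 500.004 on every array, so each array had been scaled to a common trimmed mean. Such scaling hides a change in the total amount of RNA per cell.

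Of 45101 probe sets, 34958 carried 1 gene symbol in the platform annotation, 932 carried several and 9211 were not listed. Affymetrix controls made up 64 of the 45101. Gene identifiers of 34754 probe sets matched the mouse reference gene table of the GRCm38 assembly, which changed no symbol. Genes were named only from probe sets with 1 symbol, which gave 18194 genes, 9012 of them with several probe sets. The probe set with the highest mean over the 12 arrays stood for each gene. Signals were transformed as log2(signal + 16), so changes of genes near the floor are smaller on this scale than their ratios of signal. Genes were tested if their signal lay above the 40th percentile of the array, a level of 32.9 to 41.2, on at least 3 of the 12 arrays. This left 13746 genes and removed 4448 as too dim.

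Differences were fitted with limma 3.58.1 in R 4.3.3, with lmFit on 4 group means and eBayes moderation (8 residual and 1.81 prior degrees of freedom). The 5 comparisons were white differentiation, brown differentiation, the difference between the lines in that change, brown against white adipocytes, and brown against white preadipocytes. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested. Genes with an adjusted p under 0.05 were called, and calls of at least 2-fold were counted beside them. Gene sets were tested with camera at its preset inter-gene correlation of 0.01, adjusted over the 24 lists within a comparison, and again with an estimated correlation. Counts of members adjusted over the list alone were made with the same p-values. Ratios of control probe sets were compared with exact permutation tests. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for tables, exact tests and plots.

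The 24 lists covered adipogenic transcription factors, lipid droplet and fatty acid uptake, fatty acid and triglyceride synthesis, lipolysis and its control, thermogenic and brown fat genes, white fat genes, adipokines and secreted proteins, insulin action and glucose uptake, preadipocyte genes, extracellular matrix, actin cytoskeleton and smooth muscle, and cell cycle. They also covered the respiratory chain and ATP synthase, pyruvate dehydrogenase and the citric acid cycle, fatty acid oxidation and peroxisome, branched-chain amino acid breakdown, cholesterol synthesis, inflammatory genes, interferon response, glucocorticoid response, Hox genes, and markers of macrophages, endothelial cells and skeletal muscle. Of 511 list entries, 474 matched a named gene on the array. The entry Loxl2 of the extracellular matrix list was matched to Loxl3, another gene, which was tested in its place. The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

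The text names Lrg1, Adipoq, Fabp4, Pparg, Cebpa, Slc2a4, Lep, Ucp1 and Dlk1 in each comparison where they bear on it. It also names genes from the 6 largest rises and the 6 largest falls among called genes whose arrays did not overlap between the groups, and from the 4 members of a list with the largest change. Plin1 and Cfd were part of the rule but had no probe set of their own symbol in the annotation and are not analysed here. Genes outside this rule are named as such.

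The alternatives were pseudocounts of 1 and 64, quantile normalization, equal medians, no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, probe sets of less specific design left out, an intensity trend or robust moderation in eBayes, fits of only the arrays compared, a block for the replicate number, an adjusted p under 0.01, camera with an estimated correlation, and fry, a rotation test of whether a set moves one way. Each array was left out in turn. Scaling to the hybridization controls, and leaving out the brightest genes, were added after seeing the data.

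The fit was tested on simulated data made from the white preadipocyte means and the residual spread of the 13746 genes. All 4 groups shared these means, apart from genes changed by known amounts. Of 66 genes changed by 0.5 on the log2 scale, 48.5% were recovered with the right sign for white differentiation, 50.0% for brown differentiation, 16.7% for the difference between lines, 28.8% for adipocytes and 45.5% for preadipocytes. Of 67 genes changed by 1, the shares were 71.6%, 68.7%, 55.2%, 79.1% and 71.6%, and of 67 changed by 2 they were 91.0%, 92.5%, 85.1%, 92.5% and 92.5%. Of the genes called, the share that had not been changed was 3.43%, 7.24%, 6.25%, 8.22% and 4.11% in the same order. Only 66 or 67 genes were changed by each amount, whereas the real comparisons called 50.9% to 61.2% of genes. The simulated shares therefore need not hold for the real data. Each comparison was simulated once, so differences in these shares between comparisons are not read as differences in power. The number of arrays limits the precision of every value. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these arrays, which can be technical.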

Results

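Expression was measured in mouse cell lines that turn into fat cells in culture, each before and after differentiation. 3T3-L1 is an established line of white-type preadipocytes, and the other was a brown adipocyte line. White preadipocytes were taken at day 0 and white adipocytes at day 10, brown preadipocytes at day 0 and brown adipocytes at day 8, with 3 arrays in each of the 4 groups. Both lines were induced for 3 days with IBMX (0.5 mM) and dexamethasone (1 µM). Insulin was added at 1 µg/mL to the white line and at 20 nM to the brown line, which also received indomethacin (125 µM) and T3 (1 nM), a thyroid hormone. Line, induction mix, later medium and harvest day differed together, so a difference between lines is a difference between these combinations.

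Signals are given as group means ± SD with n = 3 arrays per group, and changes as log2 differences of signal plus 16 with their SE from the limma fit. Pearson correlations of log2 signal over all probe sets were 0.978 to 0.982 between arrays of a group and 0.885 to 0.935 between groups. In a principal component analysis of the 13746 tested genes, the first component held 44.6% of the variance and ordered white preadipocytes, brown preadipocytes, white adipocytes and brown adipocytes. The second held 32.1% and separated the lines.

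Lrg1, which encodes a secreted leucine-rich glycoprotein and is named in the series title as an adipokine, rose with differentiation in both lines. In white cells its signal went from 3.49 ± 1.75 to 167 ± 9.62, a log2 change of 3.23 (SE 0.0966, adjusted p = 1.17e-09). In brown cells it went from 4.67 ± 2.28 to 1031 ± 47.4, a log2 change of 5.67 (SE 0.0966, adjusted p = 1.84e-10). The brown rise exceeded the white rise by 2.43 (SE 0.137, adjusted p = 3.09e-07), and brown adipocytes lay above white adipocytes by 2.52 (SE 0.0966, adjusted p = 9.53e-09). Preadipocytes of the lines differed by 0.08 (SE 0.0966, adjusted p = 0.51). Both preadipocyte signals lay below the 40th percentile of the arrays (32.9 to 41.2), so the size of the Lrg1 rise depends on the pseudocount: with 1 it was 5.29 in white and 7.60 in brown cells, and with 64 it was 1.77 and 3.99.

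**Figure D1:**
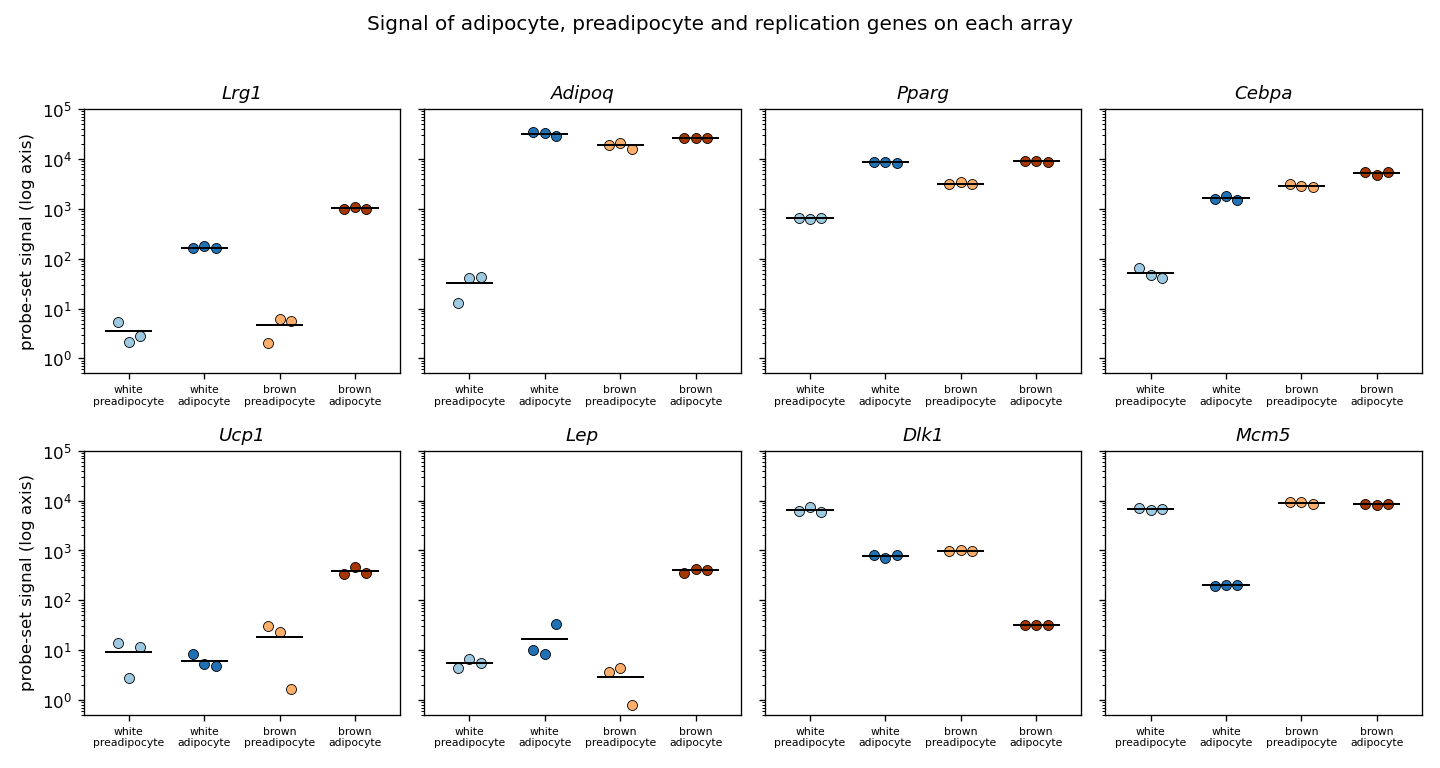
Probe-set signal on a log axis for Lrg1, Adipoq, Pparg, Cebpa, Ucp1, Lep, Dlk1 and Mcm5, with 1 point per array in each of the 4 groups and a bar at the group mean. Lrg1 went from a mean of 3.49 to 167 in white cells and from 4.67 to 1031 in brown cells, while Adipoq was already at 18695 in brown preadipocytes.

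The comparison of white adipocytes with white preadipocytes asked which genes change as 3T3-L1 cells become fat cells. G0s2, an inhibitor of triglyceride breakdown, rose from 3.26 ± 1.98 to 23896 ± 1133 (log2 change 10.28, SE 0.0861, adjusted p = 1.04e-12). Cidec, a lipid droplet protein, rose from 12.7 ± 8.29 to 23838 ± 1221, and Cd36, a fatty acid transporter, from 19.0 ± 8.43 to 22183 ± 570.1. The adipokine genes Adipoq (adiponectin) and Retn (resistin) rose to 32117 ± 2551 and 21310.0 ± 2149, by log2 changes of 9.45 (SE 0.229, adjusted p = 2.84e-10) and 8.97 (SE 0.22, adjusted p = 3.05e-10).

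Pparg, the master regulator of adipogenesis, rose from 650 ± 27.6 to 8559 ± 357, a log2 change of 3.69 (SE 0.0644, adjusted p = 4.93e-11), and Cebpa, its partner, rose by 4.63 (SE 0.132, adjusted p = 8.75e-10). Klf15, a Krüppel-like factor, rose by 7.24 (SE 0.147). Of 19 measured adipogenic transcription factors, 17 rose, 1 fell and 1 did not pass (the same 17 and 1 adjusted over the list alone, camera adjusted p = 1.29e-06). Of 17 lipid droplet and fatty acid uptake genes, 15 rose and 2 did not pass (15 adjusted over the list alone, camera adjusted p = 5.9e-09). The fatty acid binding protein Fabp4 rose by 2.42 (SE 0.0854) to 43325 ± 3292. Its probe set had the highest signal on the adipocyte arrays of both lines, so saturation, which would shrink its changes, was not excluded. Of 21 fatty acid and triglyceride synthesis genes, 20 rose and 1 fell (20 and 1 adjusted over the list alone, camera adjusted p = 3.23e-10). Thrsp, a regulator of lipogenesis, rose from 2.28 ± 1.11 to 10156 ± 1105, and the glycerol phosphate dehydrogenase Gpd1 rose by 8.16 (SE 0.268).

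All 10 measured genes of lipolysis and its control rose (10 adjusted over the list alone, camera adjusted p = 1.44e-07), among them the lipases Lipe, by 6.08 (SE 0.0918), and Pnpla2, by 4.95 (SE 0.0891). Of 16 genes of insulin action and glucose uptake, 14 rose and 2 did not pass (14 adjusted over the list alone, camera adjusted p = 9.72e-07). The insulin-responsive glucose transporter Slc2a4 rose from 30.4 ± 33.3 to 3348 ± 36.1, and hexokinase Hk2 by 3.59 (SE 0.0814). Adipokines and secreted proteins had 19 of 32 measured members up, 6 down and 7 not passed (20 up and 6 down adjusted over the list alone, camera adjusted p = 0.000141). Haptoglobin (Hp) rose by 9.11 (SE 0.116) and the acute-phase glycoprotein Orm1 by 7.72 (SE 0.127). Leptin (Lep) had signals of 5.51 ± 1.07 and 17.1 ± 13.6 (log2 change 0.55, SE 0.221, adjusted p = 0.0532). It passed the threshold without white adipocyte replicate 1 (adjusted p = 0.0372) or replicate 2 (0.017) and with the 60th percentile filter (0.0353), within a range of 0.017 to 0.139 over all alternatives.

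All 18 branched-chain amino acid breakdown genes rose (18 adjusted over the list alone, camera adjusted p = 1.22e-10), with Aldh6a1 up by 4.46 (SE 0.117) and Dbt up by 3.88 (SE 0.106). All 17 genes of pyruvate dehydrogenase and the citric acid cycle rose (17 adjusted over the list alone, camera adjusted p = 5.35e-09). Pyruvate carboxylase (Pcx) went from 541 ± 3.84 to 19108 ± 725. All 28 measured respiratory chain and ATP synthase genes rose (28 adjusted over the list alone, camera adjusted p = 1.22e-10; adjusted p = 0.0882 with an estimated correlation). Of 24 fatty acid oxidation and peroxisome genes, 22 rose, 1 fell and 1 did not pass (22 and 1 adjusted over the list alone, camera adjusted p = 3.23e-10). Thermogenic and brown fat genes rose here too, 13 of 18, with 1 down and 4 not passed (13 and 1 adjusted over the list alone, camera adjusted p = 0.000663). The mitochondrial subunits Cox8b and Cox7a1 rose by 7.97 (SE 0.273) and 5.44 (SE 0.123), whereas the uncoupling protein Ucp1 had signals of 9.41 ± 5.83 and 6.14 ± 1.94 (adjusted p = 0.671). Of 13 glucocorticoid response genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.000133).

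All 29 measured cell cycle genes fell (29 adjusted over the list alone, camera adjusted p = 4.53e-18). The replication helicase subunit Mcm5 went from 6691 ± 318 to 201.97 ± 5.82, a log2 change of −4.94 (SE 0.0628), and the DNA methylation cofactor Uhrf1 changed by −4.81 (SE 0.0981). Of 19 actin cytoskeleton and smooth muscle genes, 18 fell and 1 did not pass (18 adjusted over the list alone, camera adjusted p = 1.04e-08), with transgelin (Tagln) at −3.86 (SE 0.263) and smooth muscle actin (Acta2) at −3.27 (SE 0.145). Of 19 preadipocyte genes, 11 fell, 2 rose and 6 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0127; adjusted p = 0.0609 with an estimated correlation). Dlk1, an inhibitor of adipogenesis, fell by 3.02 on the log2 scale (SE 0.0935). The largest falls were those of the peptide hormone Cck (−6.09, SE 0.251), the differentiation inhibitor Id2 (−5.86, SE 0.105) and the BMP antagonist Grem1 (−5.39, SE 0.26).

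Of 15 white fat genes, 7 rose, 2 fell and 6 did not pass (8 and 2 adjusted over the list alone, camera adjusted p = 0.0095). Lists that did not pass were extracellular matrix (15 up, 8 down and 7 not passed of 30, camera adjusted p = 0.152), cholesterol synthesis (6, 5 and 6 of 17, adjusted p = 0.484), Hox genes (3, 7 and 12 of 22, adjusted p = 0.484) and inflammatory genes (5, 7 and 4 of 16, adjusted p = 0.399). Adjusted over the list alone the counts up and down were 15 and 8, 6 and 5, 1 and 6, and 5 and 7. Within the matrix list, lumican (Lum) rose by 6.41 (SE 0.396) while the protease inhibitor Timp1 fell by 3.78 (SE 0.0745). The interferon response list (10 up, 1 down and 6 not passed of 17, and 10 and 1 adjusted over the list alone) had a camera adjusted p of 0.056. It passed without white preadipocyte replicate 2 (0.0392) or white adipocyte replicate 2 (0.0375). It also passed with equal medians (0.0403), no filter (0.0332), the mean of probe sets (0.0232), hybridization-control scaling (0.0311) and the brightest genes left out (0.047), in a range of 0.0232 to 0.51 over alternatives that kept camera. Markers of macrophages (1 up, 2 down and 4 not passed of 7, also adjusted over the list alone), endothelial cells (1 up and 2 not passed of 3, with 0 adjusted over the list alone) and skeletal muscle (4 up, 2 down and 3 not passed of 9, also adjusted over the list alone) had camera adjusted p of 0.576, 0.853 and 0.53. For skeletal muscle markers the mean (−0.00373) had the opposite sign to the median (0.29) and the test.

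In all, 8413 of 13746 genes were called, 4130 up and 4283 down, and 1820 rose and 1706 fell at least 2-fold. Arrays of the groups did not overlap for 66% of the genes tested, against 10% by chance. Scaled to the hybridization controls, the calls were 2905 up and 5682 down, since the median change of all genes moved from 0.02 to −0.23, and equal medians moved it to −0.09. The 3'/5' signal ratio of the beta-actin control was 1.40 ± 0.0554 before and 2.25 ± 0.151 after differentiation (n = 3, exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). The ratio of pyruvate carboxylase rose too, from 3.63 ± 0.693 to 7.64 ± 1.83 (exact permutation p = 0.1). That of Gapdh did not, going from 0.861 ± 0.0342 to 0.828 ± 0.00689 (exact permutation p = 0.1). Of the spiked poly-A control RNAs only dap was tested, with ratios of 4.45 ± 1.03 and 4.28 ± 0.274 (exact permutation p = 0.9).

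The comparison of brown adipocytes with brown preadipocytes asked the same question in the brown line. Myoglobin (Mb), an oxygen-binding protein of oxidative tissue, had the largest named rise, from 18.8 ± 15.3 to 15336 ± 1650.0 (log2 change 8.88, SE 0.453, adjusted p = 7.44e-08). Cidea, a lipid droplet protein of brown fat, rose from 10.4 ± 10.5 to 6754 ± 337, and the mitochondrial protein Chchd10 from 129 ± 29.7 to 24135 ± 708. Ucp1, which uncouples respiration in brown fat, rose from 18.3 ± 14.9 to 382 ± 74.5, a log2 change of 3.64 (SE 0.325, adjusted p = 4.62e-06).

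Of 18 thermogenic and brown fat genes, 13 rose and 5 did not pass (13 adjusted over the list alone, camera adjusted p = 8.88e-07). Cox8b and Cox7a1 rose by 7.13 (SE 0.273) and 7.06 (SE 0.123), and the fatty acid sensor Ppara by 3.81 (SE 0.136). All 17 genes of pyruvate dehydrogenase and the citric acid cycle rose (17 adjusted over the list alone, camera adjusted p = 6.22e-11). Of 28 respiratory chain and ATP synthase genes, 27 rose and 1 did not pass (27 adjusted over the list alone, camera adjusted p = 5.27e-12; adjusted p = 0.0669 with an estimated correlation). Fatty acid oxidation and peroxisome genes rose in 21 of 24 cases, fell in 2 and did not pass in 1 (21 and 2 adjusted over the list alone, camera adjusted p = 3.23e-09). All 18 branched-chain amino acid breakdown genes rose (18 adjusted over the list alone, camera adjusted p = 6.85e-10).

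Pparg, Cebpa and Fabp4 rose from a higher signal than in white cells. Pparg went from 3188 ± 167 to 8998 ± 279, a log2 change of 1.49 (SE 0.0644, adjusted p = 2.37e-08), Cebpa rose by 0.84 (SE 0.132, adjusted p = 0.000313) and Fabp4 by 0.54 (SE 0.0854, adjusted p = 0.000299). Adipoq stood at 18695 ± 2319 before and 26332 ± 497 after differentiation (log2 change 0.50, SE 0.229, adjusted p = 0.085). It passed with a pseudocount of 64 (adjusted p = 0.00488), with an intensity trend (0.024) and in the fit of only the arrays compared (0.00849), within 0.00488 to 0.266 over all alternatives. Of 19 adipogenic transcription factors, 13 rose, 3 fell and 3 did not pass (13 and 3 adjusted over the list alone, camera adjusted p = 0.000672). The coactivator Ppargc1b rose by 3.72 (SE 0.101) and the carbohydrate-sensing factor Mlxipl by 3.69 (SE 0.284). Of 17 lipid droplet and fatty acid uptake genes, 14 rose, 1 fell and 2 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.47e-06; adjusted p = 0.0504 with an estimated correlation). Fatty acid and triglyceride synthesis had 18 of 21 genes up, 1 down and 2 not passed (18 and 1 adjusted over the list alone, camera adjusted p = 6.06e-08). All 10 genes of lipolysis and its control rose (10 adjusted over the list alone, camera adjusted p = 1.19e-06), with the phosphodiesterase Pde3b up by 4.47 (SE 0.0897). Of 16 genes of insulin action and glucose uptake, 12 rose and 4 did not pass (12 adjusted over the list alone, camera adjusted p = 2.89e-06), with Slc2a4 up by 2.86 (SE 0.391). Adipokines and secreted proteins had 17 of 32 members up, 7 down and 8 not passed (17 and 7 adjusted over the list alone, camera adjusted p = 0.00492). Leptin (Lep) rose from 2.97 ± 1.91 to 398 ± 32.3, while the chemokine Cxcl12 fell by 4.49 (SE 0.103). Of 13 glucocorticoid response genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 8.55e-05).

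Genes of matrix, precursor state and contractility fell. The growth factor Ptn went from 26543 ± 1520.0 to 66.0 ± 13.8, a log2 change of −8.35 (SE 0.123, adjusted p = 8.01e-11), and the Wnt modulator Sfrp2 changed by −7.97 (SE 0.222) and the matrix protein Ogn by −7.17 (SE 0.155). Of 30 extracellular matrix genes, 23 fell, 2 rose and 5 did not pass (23 and 2 adjusted over the list alone, camera adjusted p = 1.09e-09). Periostin (Postn) changed by −6.10 (SE 0.139) and collagen Col1a2 by −4.85 (SE 0.092). Of 19 preadipocyte genes, 16 fell, 1 rose and 2 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 1.94e-06), including the progenitor receptor Pdgfra at −5.23 (SE 0.0964) and Dlk1 at −4.38 (SE 0.0935). All 19 actin cytoskeleton and smooth muscle genes fell (19 adjusted over the list alone, camera adjusted p = 1.57e-09).

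Interferon response genes fell in 14 of 17 cases, rose in 2 and did not pass in 1 (14 and 2 adjusted over the list alone, camera adjusted p = 1.58e-05; adjusted p = 0.0878 with an estimated correlation), with the antiviral gene Ifit1 at −5.12 (SE 0.175). Of 17 cholesterol synthesis genes, 15 fell and 2 rose (15 and 2 adjusted over the list alone, camera adjusted p = 8.55e-05; adjusted p = 0.0878 with an estimated correlation), with the mevalonate pathway enzyme Mvd at −1.88 (SE 0.111). Of 29 cell cycle genes, 19 fell, 1 rose and 9 did not pass (19 and 1 adjusted over the list alone, camera adjusted p = 0.000605; adjusted p = 0.0872 with an estimated correlation). Cyclin D1 (Ccnd1) fell by 2.92 (SE 0.0975), while Mcm5 stood at 8998 ± 473 and 8533 ± 211. Of 22 Hox genes, 11 fell, 1 rose and 10 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 0.0165), a call lost at a pseudocount of 1 (adjusted p = 0.0551, range 0.00733 to 0.0551 over alternatives that kept camera). Inflammatory genes (5 up, 9 down and 2 not passed of 16, and 5 and 9 adjusted over the list alone) and white fat genes (6 up, 5 down and 4 not passed of 15, and 6 and 6 adjusted over the list alone) had camera adjusted p of 0.114 and 0.802. The inflammatory list passed with the 60th percentile filter (0.046) and with the brightest genes left out (0.0337), in a range of 0.0337 to 0.273 over alternatives that kept camera. Markers of macrophages (2 down and 5 not passed of 7), endothelial cells (3 not passed of 3) and skeletal muscle (2 up, 2 down and 5 not passed of 9), with the same counts adjusted over the list alone, each had a camera adjusted p of 0.954. In each the median and the mean differed in sign. In the white fat list, median (−0.12) and mean (−0.19) were opposite in sign to the test.

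Calls numbered 8062 of 13746 genes, 3734 up and 4328 down, with 1327 up and 1726 down at least 2-fold, and the groups did not overlap for 65.2% of genes against 10% by chance. With scaling to the hybridization controls, 2717 were up and 5472 down, and the median change of all genes moved from −0.03 to −0.20. The beta-actin 3'/5' ratio was 1.49 ± 0.0626 before and 2.42 ± 0.0478 after differentiation (n = 3, exact permutation p = 0.1, two-sided), that of Gapdh 0.775 ± 0.0296 and 0.814 ± 0.0189 (exact permutation p = 0.2), and that of pyruvate carboxylase 5.70 ± 0.902 and 6.80 ± 0.763 (exact permutation p = 0.2). The ratio of the spiked control dap fell from 4.62 ± 0.525 to 3.97 ± 0.154 (exact permutation p = 0.1).

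**Figure D2:**
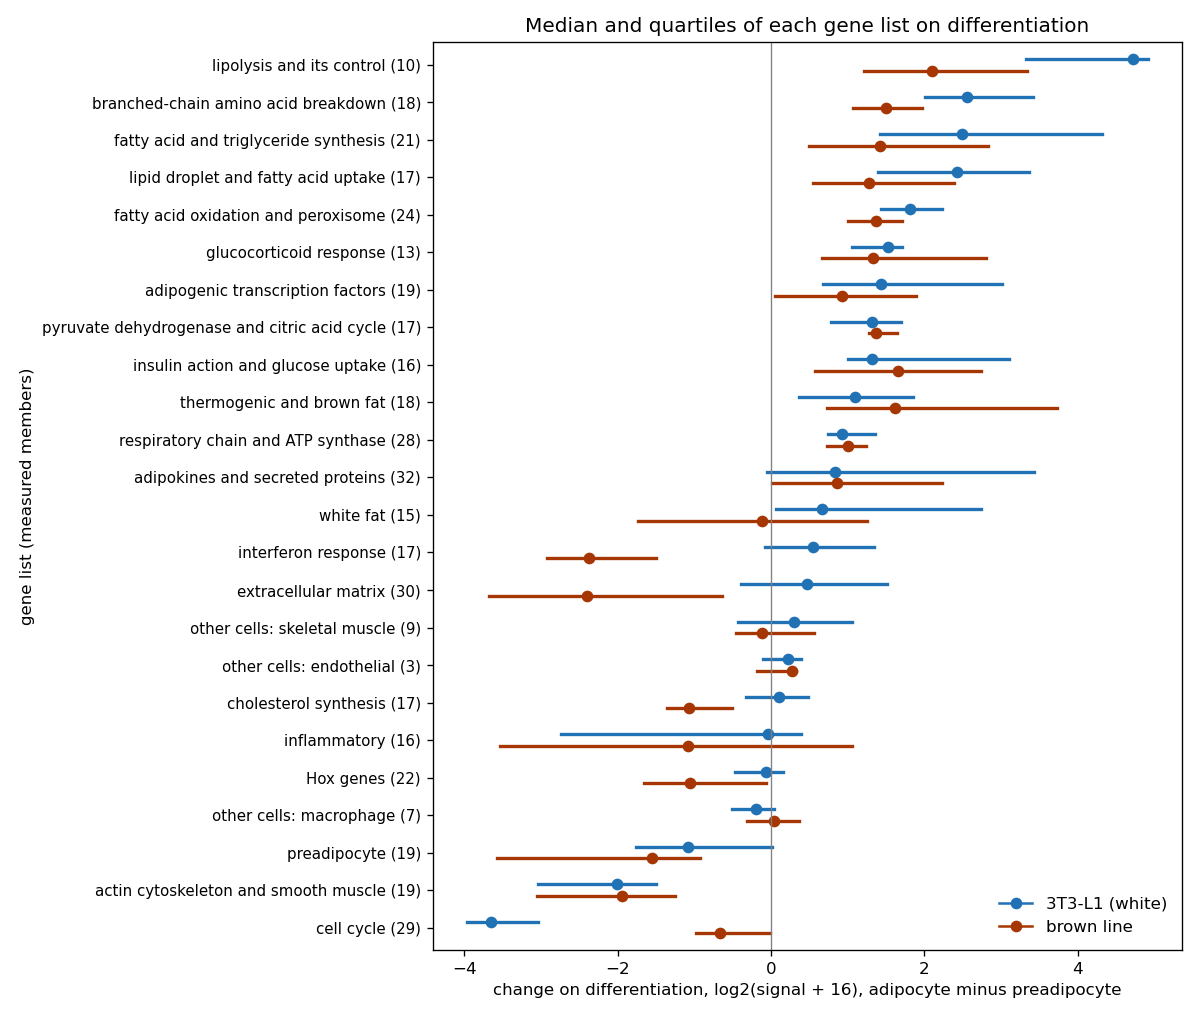
Log2 change with differentiation of the members of the 24 gene lists, with 3T3-L1 in blue and the brown line in brown; points are list medians, lines run between the quartiles, and brackets hold the number of measured members. The cell cycle median was −3.65 in 3T3-L1 and −0.66 in the brown line, and the extracellular matrix median 0.47 and −2.40.

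Calls of both lines were compared to ask which changes they shared. The largest shared rises, ranked by the smaller of both changes, were Cox8b (7.97 in white and 7.13 in brown), the carboxylesterase Ces1d (6.74 and 6.66), Thrsp (9.12 and 5.45) and Cox7a1 (5.44 and 7.06). Among shared falls were the membrane protein Tm4sf1 (−4.82 and −5.41), the monocyte chemoattractant Ccl2 (−4.54 and −4.37) and the annexin Anxa3 (−4.95 and −4.01). In total 2299 genes rose in both lines, against 1122 for independent sets of calls, and 2470 fell in both, against 1349 (1348.5). Changes of at least 2-fold were shared by 744 rises (175.7 for independent calls) and 631 falls (214.2). Opposite calls were fewer than for independent sets, with 669 up in white and down in brown against 1300 (1300.4) and 507 the other way against 1163. Across the 13746 genes the changes had a Pearson r of 0.478 and a Spearman rho of 0.472, in which genes are not independent replicates. Both comparisons shared no arrays, but they came from 1 fit with 1 estimate of spread per gene. A gene with a small spread is thus more easily called in both lines, and the counts for independent sets are only a reference. With scaling to the hybridization controls, 1531 genes rose in both lines.

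The difference between the lines in the change with differentiation was tested directly, as the brown change minus the white change. Adipoq, Cebpa and Pparg had smaller changes in brown cells, where their preadipocyte signal was higher. Adipoq differed by −8.95 (SE 0.323, adjusted p = 1.81e-08), Cebpa by −3.80 (SE 0.187, adjusted p = 1.24e-07) and Pparg by −2.19 (SE 0.0911, adjusted p = 4.45e-08). Mcm5 differed by 4.87 (SE 0.0889, adjusted p = 1.08e-09), having fallen in white cells from 6691 ± 318 to 201.97 ± 5.82. Cidea (6.68, SE 0.548, adjusted p = 4.27e-06) and Mb (5.56, SE 0.641, adjusted p = 4.84e-05) rose more in brown than in white cells. Ucp1 (3.81, SE 0.459, adjusted p = 6.6e-05) rose in brown cells without a called rise in white cells.

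All 29 cell cycle genes had a positive difference that passed (29 adjusted over the list alone, camera adjusted p = 2.25e-21), a call kept with an estimated correlation (adjusted p = 0.00749). Extracellular matrix genes had 24 of 30 negative differences, 1 positive and 5 not passed (24 and 1 adjusted over the list alone, camera adjusted p = 5.98e-12; adjusted p = 0.0973 with an estimated correlation). Periostin (Postn) rose in white cells from 4156 ± 472 to 14373 ± 2519 and fell in brown cells from 12086 ± 330.2 to 162 ± 24.4, a difference of −7.88 (SE 0.197). The matrix protease Mmp2 went the same ways, with a difference of −7.62 (SE 0.184). Interferon response genes differed negatively in 16 of 17 cases and positively in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 2.89e-07; adjusted p = 0.0973 with an estimated correlation), with Ifit1 at −5.74 and the interferon regulator Usp18 at −5.69.

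Another 9 lists passed, each with more negative than positive differences and each lost with an estimated correlation (adjusted p of 0.0973 for adipokines and secreted proteins, branched-chain amino acid breakdown, cholesterol synthesis, lipid droplet and fatty acid uptake, lipolysis and its control, preadipocyte and white fat genes, 0.134 for fatty acid and triglyceride synthesis, and 0.162 for fatty acid oxidation and peroxisome). With the brightest genes left out, the lipid droplet list (adjusted p from 1.51e-05 to 0.102, range 2e-06 to 0.102) and the adipokine list (from 0.0186 to 0.331, range 0.00503 to 0.331) lost their calls. The adipokine list also lost its call with the replicate block (0.053). The acyltransferase Gpat3 (−5.13, SE 0.151), Gpd1 (−4.63, SE 0.378), the short-chain fatty acid receptor Ffar2 (−3.94) and Lipe (−3.15) stood among their members. Angiotensinogen (Agt), a blood pressure hormone precursor, rose in white cells from 11.8 ± 7.29 to 4479 ± 157 and fell in brown cells from 3249 ± 377 to 387 ± 70.0, a difference of −10.40 (SE 0.254, adjusted p = 2.7e-09). The apolipoprotein Apod and the antimicrobial peptide Camp behaved alike, at −10.54 (SE 0.503) and −10.13 (SE 0.288). Dlk1 differed by −1.36 (SE 0.132, adjusted p = 1.41e-05), but by 0.95 where its less specific probe set was left out, and its other probe sets averaged in gave no call (adjusted p = 0.322), within 1.78e-07 to 0.322 over all alternatives. Of 13746 genes, 7001 were called, 3240 with a positive and 3761 with a negative difference, and 1347 and 1990 of them at least 2-fold. The larger side turned with the scaling: 3753 were positive and 3021 negative with equal medians, which moved the median difference of all genes from −0.05 to 0.08, and 3551 and 3225 with scaling to the hybridization controls.

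Lists of fat cell genes did not all move one way. Adipogenic transcription factors had 6 positive and 10 negative differences and 3 not passed of 19 (6 and 10 adjusted over the list alone, camera adjusted p = 0.142, but 0.0323 with the brightest genes left out, range 0.0323 to 0.217), and insulin action and glucose uptake 4, 8 and 4 of 16 (4 and 8 adjusted over the list alone, camera adjusted p = 0.508). Thermogenic and brown fat genes had 7 positive and 2 negative differences and 9 not passed of 18 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0514). That list passed without white preadipocyte replicate 2 (0.0423) or 3 (0.0289), without brown preadipocyte replicate 3 (0.0376) and without brown adipocyte replicate 1 (0.041). It also passed with a pseudocount of 64 (0.014), quantile normalization (0.035), no filter (0.0334), the 60th percentile filter (0.0448), the mean of probe sets (0.0241) and less specific probe sets left out (0.0495). The range was 0.014 to 0.214 over alternatives that kept camera. Hox genes had 6 negative differences and 16 not passed of 22 (6 adjusted over the list alone, camera adjusted p = 0.103, but 0.038 with a pseudocount of 64, range 0.038 to 0.398). The other 8 lists that did not pass had camera adjusted p of 0.53 to 0.906.

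Brown and white adipocytes were compared to find what separates the fat cell types once differentiated. Zic1, a transcription factor of brown fat precursors, was at 3790 ± 192 in brown and 4.62 ± 2.95 in white adipocytes (log2 difference 7.54, SE 0.153, adjusted p = 2.22e-10). Prdm16, a coregulator that specifies brown fat, was at 696 ± 27.4 and 1.76 ± 1.03 (adjusted p = 4.02e-09, but 0.0521 with a pseudocount of 1, range 1.54e-12 to 0.0521), and Ucp1 was higher by 4.16 (SE 0.325, adjusted p = 1.62e-06). The largest difference was that of the retinol carrier Rbp4, at 20785 ± 619 in brown and 49.9 ± 19.7 in white adipocytes. Adipoq (−0.28, SE 0.229, adjusted p = 0.318), Fabp4 (−0.12, SE 0.0854, adjusted p = 0.268), Pparg (0.07, SE 0.0644, adjusted p = 0.366) and Slc2a4 (−0.20, SE 0.391, adjusted p = 0.697) did not pass.

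Thermogenic and brown fat genes were higher in brown adipocytes for 13 of 18 members, lower for 1 and not passed for 4 (13 and 1 adjusted over the list alone, camera adjusted p = 6.14e-05), a call kept with an estimated correlation (adjusted p = 0.0168). Cell cycle genes were higher for 28 of 29 and lower for 1 (28 and 1 adjusted over the list alone, camera adjusted p = 6.49e-17, and adjusted p = 0.0163 with an estimated correlation), with Mcm5 higher by 5.29 (SE 0.0628) and Mcm6 by 4.48 (SE 0.0841). Extracellular matrix genes were lower for 24 of 30, higher for 4 and not passed for 2 (24 and 4 adjusted over the list alone, camera adjusted p = 8.92e-09; adjusted p = 0.128 with an estimated correlation). The proteoglycan decorin (Dcn) was at 6408 ± 874 in white and 5.47 ± 1.92 in brown adipocytes. Cholesterol synthesis genes were lower for 16 of 17 and not passed for 1 (16 adjusted over the list alone, camera adjusted p = 2.88e-07; adjusted p = 0.128 with an estimated correlation), for example the desaturase Sc5d (−2.24, SE 0.0804). Preadipocyte genes were lower for 12 of 19, higher for 1 and not passed for 6 (12 and 2 adjusted over the list alone, camera adjusted p = 0.00119; adjusted p = 0.0693 with an estimated correlation), including the surface glycoprotein Thy1 (−4.89, SE 0.188). Interferon response genes were higher for 11 of 17 and not passed for 6 (11 adjusted over the list alone, camera adjusted p = 0.00719; adjusted p = 0.561 with an estimated correlation), led by the immunoproteasome subunit Psmb8 (4.18, SE 0.0807).

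Respiratory chain and ATP synthase genes were higher for 13 of 28, lower for 1 and not passed for 14 (13 and 1 adjusted over the list alone, camera adjusted p = 0.0596). That list passed in 8 alternatives that kept camera, among them quantile normalization (2.25e-05), hybridization-control scaling (0.00241), the mean of probe sets (0.0101) and white adipocyte replicate 1 left out (0.0333). The range was 2.25e-05 to 0.684. Branched-chain amino acid breakdown genes were higher for 2 of 18, lower for 10 and not passed for 6 (3 and 10 adjusted over the list alone, camera adjusted p = 0.0661). They passed with equal medians (0.0255), no filter (0.0327) and without white adipocyte replicate 3 (0.0496), in a range of 0.0255 to 0.561. Pyruvate dehydrogenase and citric acid cycle genes were higher for 9 of 17, lower for 3 and not passed for 5 (9 and 3 adjusted over the list alone, camera adjusted p = 0.414, but 0.0202 with quantile normalization, range 0.0202 to 0.716). White fat genes were higher for 5 of 15, lower for 7 and not passed for 3 (5 and 7 adjusted over the list alone, camera adjusted p = 0.562). The other 14 lists had camera adjusted p of 0.392 to 0.967.

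Among single genes, the metalloprotease Mme (7.66, SE 0.153) and the cell cycle inhibitor Cdkn1c (7.02, SE 0.106) had some of the largest differences upward. Cdkn1c belongs to the glucocorticoid response list, which did not pass. Ptn (−7.75, SE 0.123), the cadherin Cdh11 (−6.77, SE 0.145) and the transcription factor Maf (−6.62, SE 0.216) were among the largest downward. Genes called numbered 8177, 4125 higher and 4052 lower in brown adipocytes, with 1625 and 1530 at least 2-fold. Arrays did not overlap for 65.5% against 10% by chance. Under scaling to the hybridization controls the calls were 4958 higher and 3131 lower, and the median difference of all genes moved from 0.00054 to 0.14. Equal medians moved it to −0.12 and turned the larger side, with 3426 higher and 4688 lower. Quantile normalization turned it too, with 3867 higher and 4412 lower. Fabp4 passed with equal medians (adjusted p = 0.026, range 0.026 to 1) and Pparg with quantile normalization or hybridization-control scaling (0.00691 and 0.00618, range 0.00618 to 0.686). Adipoq (0.0249, range 0.0249 to 0.783) and Slc2a4 (0.0382, range 0.0382 to 0.954) passed in the fit of only the arrays compared.

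**Figure D3:**
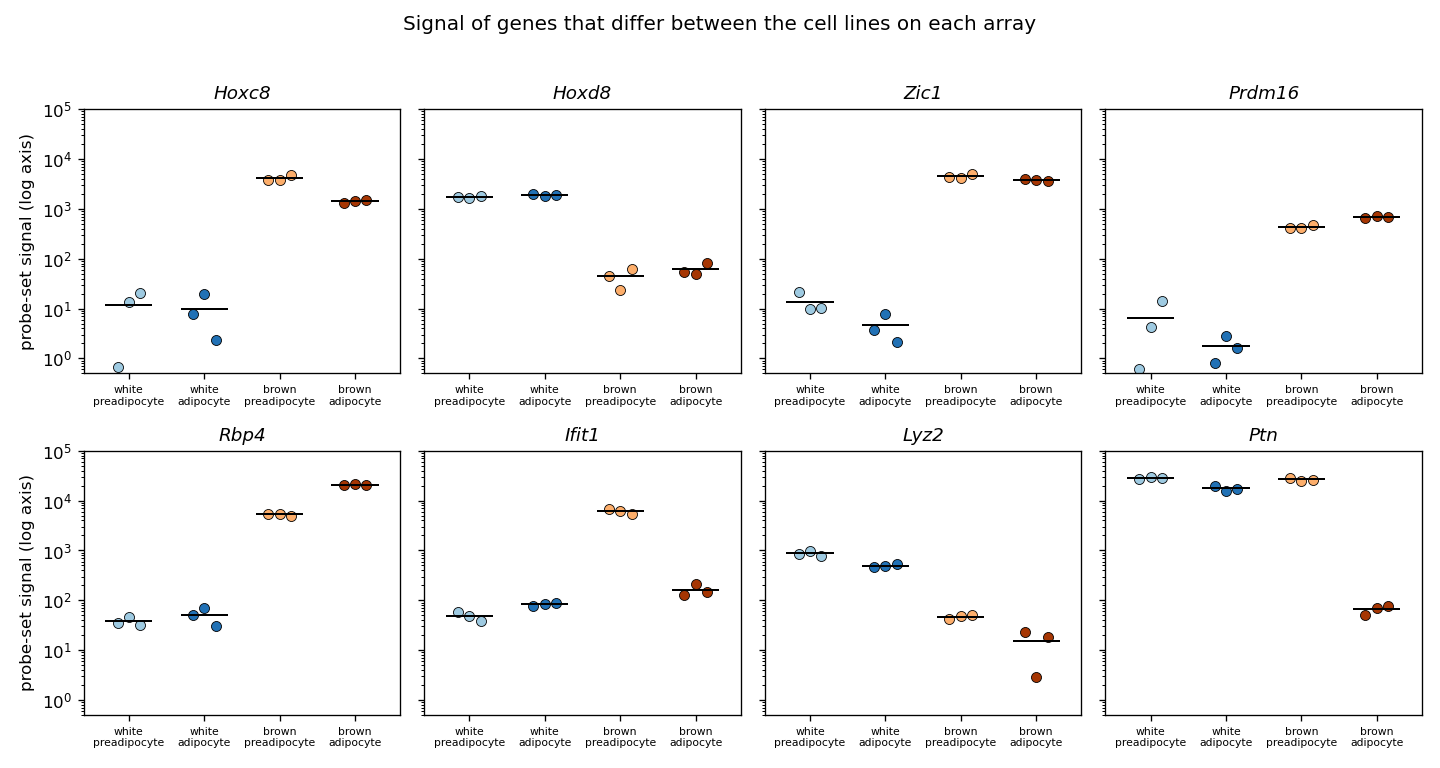
Probe-set signal on a log axis for Hoxc8, Hoxd8, Zic1, Prdm16, Rbp4, Ifit1, Lyz2 and Ptn, with 1 point per array in each of the 4 groups and a bar at the group mean. Hoxc8 lay at 4156 and 1432 in brown cells and at 11.7 and 10.0 in white cells, and Hoxd8 lay the other way round.

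Brown and white preadipocytes were compared to ask what separated the lines before induction. Adipoq was at 18695 ± 2319 against 31.9 ± 16.4 in white preadipocytes (log2 difference 8.67, SE 0.229, adjusted p = 1.54e-09), the carbonic anhydrase Car3 at 23650.0 ± 1523 against 16.1 ± 15.7, and Cebpa at 2917 ± 169 against 50.7 ± 12.5. Lrg1 did not share this difference, at 4.67 ± 2.28 and 3.49 ± 1.75. Of the Hox genes, which mark position along the body axis, Hoxc8 was higher in brown preadipocytes by 7.30 (SE 0.299, adjusted p = 2.66e-08) and Hoxd8 was lower, with a log2 difference of −4.90 (SE 0.227, adjusted p = 6.15e-08).

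All 17 interferon response genes were higher in brown preadipocytes (17 adjusted over the list alone, camera adjusted p = 4.92e-10; adjusted p = 0.0852 with an estimated correlation). Ifit1 was at 6140.4 ± 738 against 48.3 ± 9.53, and the interferon-inducible GTPase Iigp1 at 4565 ± 461 against 50.4 ± 5.62. Adipogenic transcription factors were higher for 12 of 19, lower for 4 and not passed for 3 (12 and 4 adjusted over the list alone, camera adjusted p = 0.0154; adjusted p = 0.0852 with an estimated correlation). Fatty acid and triglyceride synthesis genes were higher for 18 of 21 and not passed for 3 (18 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.87e-07; adjusted p = 0.0852 with an estimated correlation). Lipolysis genes were higher for 8 of 10 (8 adjusted over the list alone, camera adjusted p = 0.00131), adipokines for 17 of 32 with 2 lower (17 and 2 adjusted over the list alone, camera adjusted p = 0.00187), and white fat genes for 10 of 15 with 2 lower (10 and 2 adjusted over the list alone, camera adjusted p = 0.0112). Thermogenic genes were higher for 9 of 18 with 2 lower (9 and 2 adjusted over the list alone, camera adjusted p = 0.0167), among them Zic1 by 7.28 (SE 0.153) and Ebf2 by 3.73 (SE 0.0649), while Ucp1 did not pass (0.35, SE 0.325, adjusted p = 0.405). These last 4 lists each had an adjusted p = 0.0852 with an estimated correlation. The adipokine call was also lost with the brightest genes left out (0.101, range 0.00018 to 0.101). The thermogenic call was lost with a pseudocount of 1 (0.0637, range 0.000775 to 0.0852). Ucp1 passed without brown preadipocyte replicate 3 (adjusted p = 0.0142), within 0.0142 to 0.882 over all alternatives.

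Lipid droplet and fatty acid uptake genes were higher for 11 of 17 and lower for 1 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000153; adjusted p = 0.15 with an estimated correlation). Fatty acid oxidation and peroxisome genes were higher for 18 of 24 with 2 lower (18 and 3 adjusted over the list alone, camera adjusted p = 0.00221; adjusted p = 0.165 with an estimated correlation). Branched-chain amino acid breakdown genes were higher for 10 of 18 with 1 lower (10 and 1 adjusted over the list alone, camera adjusted p = 0.0187; adjusted p = 0.23 with an estimated correlation). Extracellular matrix genes were higher for 18 of 30 and lower for 7 (19 and 8 adjusted over the list alone, camera adjusted p = 0.0235; adjusted p = 0.442 with an estimated correlation and 0.415 with the brightest genes left out, range 0.00163 to 0.442). Cell cycle genes were higher for 15 of 29 and lower for 2 (15 and 2 adjusted over the list alone, camera adjusted p = 0.0379; adjusted p = 0.342 with an estimated correlation). That call was lost with equal medians (adjusted p = 0.399), without white preadipocyte replicate 2 (0.0754) and without brown preadipocyte replicate 2 (0.0527). It was also lost with the 60th percentile filter (0.0569), the mean of probe sets (0.0539) and the brightest genes left out (0.0645), in a range of 0.00123 to 0.399 over alternatives that kept camera. Hox genes were higher for 14 of 22 and lower for 4 (14 and 4 adjusted over the list alone) with a camera adjusted p of 0.0514, and of 0.0477 without white preadipocyte replicate 3. It passed too with equal medians (0.00712), a pseudocount of 64 (0.0185), no filter (0.0341), only the arrays compared (0.0247) and the replicate block (0.0377) (range 0.00712 to 0.126 over alternatives that kept camera).

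Respiratory chain and ATP synthase genes were higher for 14 of 28, lower for 2 and not passed for 12 (14 and 2 adjusted over the list alone, camera adjusted p = 0.0603). They passed with quantile normalization (0.000382), no filter (0.0279), hybridization-control scaling (0.0194), less specific probe sets left out (0.0382) and without brown preadipocyte replicate 3 (0.0181). The range was 0.000382 to 0.776. Of the other lists that did not pass, 9 had camera adjusted p of 0.129 to 0.97. Of macrophage markers, 1 of 7 was higher, 2 lower and 4 not passed (1 and 2 adjusted over the list alone, camera adjusted p = 0.186, but 0.0497 with the 60th percentile filter, range 0.0497 to 0.538), and lysozyme (Lyz2) was at 46.5 ± 4.48 in brown and 870 ± 95.8 in white preadipocytes. The surface glycoprotein Thy1 (−5.22, SE 0.188), Cck (−7.33, SE 0.251), Cdh11 (−6.83, SE 0.145) and the guidance factor Slit2 (−6.41, SE 0.338) were lower in brown preadipocytes. In all 7547 genes were called, 4277 higher and 3270 lower in brown preadipocytes, with 1573 and 858 at least 2-fold. The groups did not overlap for 61.8% of genes against 10% by chance. With equal medians, 2704 were higher and 4949 lower, and the median difference of all genes moved from 0.07 to −0.18. Scaling to the hybridization controls moved it the other way, to 0.13, with 4661 higher and 2803 lower. Quantile normalization gave 3790 higher and 3649 lower, with a median of −0.01.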

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

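The 6 tests that weigh explanations for a pattern in this part were chosen after the result was seen, while the tests on other splits of the arrays were planned. Results stand here because they differed between the groups compared, in that the brown change minus the white change passed its test, or because they come from probe sets that no gene name covers. With 3 arrays in each group, no single array was tested for standing apart from its group.

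The change with differentiation differed between the lines for 7001 genes. Among cell cycle genes the median difference was 2.70, the only list of these 12 with a positive median. The others were negative: adipokines and secreted proteins −0.743, branched-chain amino acid breakdown −0.915, cholesterol synthesis −1.24, extracellular matrix −2.33, fatty acid and triglyceride synthesis −1.69, fatty acid oxidation and peroxisome −0.594, interferon response −2.67, lipid droplet and fatty acid uptake −1.60, lipolysis and its control −1.64, preadipocyte −0.907 and white fat −0.830. With an estimated correlation these 11 negative lists lost their calls (adjusted p of 0.0973 to 0.162), and cell cycle kept its call (adjusted p = 0.00749).

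Lrg1 rose more in brown than in white cells, with a difference of 2.43, as did Cidea (6.68) and Mb (5.56). Lep (3.90) and Ucp1 (3.81) rose in brown cells without a called rise in white cells. For Adipoq (−8.95), Fabp4 (−1.88), Pparg (−2.19), Cebpa (−3.80), Slc2a4 (−3.55) and G0s2 (−8.76) the difference was negative, and each had a higher signal in brown than in white preadipocytes. Npnt, an integrin ligand, fell in white cells from 1759.5 ± 63.7 to 107 ± 16.8 and rose in brown cells from 137 ± 5.18 to 835 ± 4.999, a difference of 6.34. Cck (5.70) and Id2 (5.49) were high in white preadipocytes and fell there.

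Rises in white cells and falls in brown cells marked Apod (−10.54), Agt (−10.40), Camp (−10.13) and the matrix proteins Aspn (−9.09), Postn (−7.88), Mmp2 (−7.62) and Dpt (−7.63). Among metabolic genes the differences were −2.41 for Aldh6a1, −2.20 for Ivd, −2.56 for Dhcr7, −1.88 for Cyp51, −5.13 for Gpat3, −4.63 for Gpd1, −2.54 for Acot1, −1.46 for Pex19, −3.94 for Ffar2 and −3.15 for Lipe. Ifit1 (−5.74) and Usp18 (−5.69) of the interferon response, the progenitor genes Pdgfra (−5.42), Sfrp2 (−4.68) and Dlk1 (−1.36), and the cell cycle genes Mcm5 (4.87) and Uhrf1 (4.53) complete these results. The Dlk1 value rests on its probe set: the difference was 0.945 with the less specific probe set left out.

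Probe sets without a gene name were tested apart from the named genes, 5400 of them. Of these, 472 were higher at least 2-fold after white differentiation and 490 after brown differentiation, and 1668 and 1711 were called in either direction. Whether they measure other transcripts than the named probe sets was not tested.

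Some adipocyte genes were already high in brown preadipocytes, where Adipoq had 71.0%, Cebpa 55.8%, G0s2 34.7% and Slc2a4, the lowest of the 10 genes compared, 13.8% of its brown adipocyte signal; Plagl1 and Kng1 among the 10 fell with brown differentiation. Adipocytes like those harvested at day 8, mixed into these cultures, would carry all fat cell transcripts in a similar share. The 6 largest brown rises, among them Mb and Cidea, stood at 0.648% or less, so cells of that profile cannot be the whole source. These 6 genes were chosen from the same data for their rise, and adipocytes of another profile are not excluded. A swapped label of single brown arrays is excluded, since no brown preadipocyte array correlated with a brown adipocyte array above 0.929. Brown arrays of a group correlated at 0.980 or more. An exchange of whole groups would leave these correlations unchanged and was not tested by them. A property of the brown line, or cells that express Adipoq without Cidea, may account for the pattern, and neither was tested.

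Interferon response genes were high in brown preadipocytes, with a median log2 difference of 3.95 from white preadipocytes and a lower quartile of 2.20, a list call that was lost with an estimated correlation (adjusted p = 0.0852). Macrophages in the brown cultures would raise their own markers, but the median difference of 7 such markers was −0.346 (SD 1.503). Array scaling is excluded as the cause, since the median stayed at 3.71 or more under 3 other scalings. An activated interferon response as a property of the brown line is a possible explanation that was not tested.

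Cell cycle genes fell less in brown than in white differentiation. Cells with the day 0 profile left among the brown adipocytes would keep precursor transcripts at the same share. The 6 largest brown falls, among them Ptn and Sfrp2, kept at most 0.854% of their brown preadipocyte signal. The 29 cell cycle genes kept a median of 63.0% and at least 11.1%. These 6 genes were chosen from the same data for their fall. Cells that were induced but did not differentiate need not keep the day 0 profile and are not excluded. Array scaling is excluded, since the median difference stayed at 2.49 or more under 3 other scalings. Line, medium and harvest day differ together here, so which of them could set the level of cell cycle transcripts was not tested.

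Other splits of the arrays were counted for each comparison. The 10 splits of 6 arrays are too few for a share under 0.05. In fits of only those 6 arrays, white differentiation had 8154 genes called and 0 at most in another split, with 1 split as large, the real one. Brown differentiation had 7810 against 0 (1 split), brown against white adipocytes 7997 against 0 (1 split), and brown against white preadipocytes 7098 against 0 (1 split). For gene lists past the threshold the real and highest other counts were 16 and 17 in white differentiation (2 splits as large), 19 and 18 in brown differentiation (1 split), 7 and 5 in adipocytes (1 split) and 13 and 7 in preadipocytes (1 split). Lists therefore also passed in regrouped arrays under camera's preset correlation. Every other split mixes arrays of the groups unevenly, so part of the real difference stays between its sides. Lists can pass because of that part, so these splits cannot tell whether the preset correlation gives false list calls. The rest of the difference goes into the residual spread, so the counts of 0 genes are not taken to exclude chance.

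For the difference between lines, 1 of 100 drawn splits reached the 7001 genes called, the real one, and the highest other count was 3988. For its gene lists, 3 of 100 splits reached the real count of 12, and the highest other count was 12. The drawn splits mix the lines within 1 stage or within both, which puts the difference between lines into the residual spread. A split that mixes 1 stage keeps the whole difference between lines in the other. That difference then enters the value tested and can by itself give many calls. Whether the split with 3988 calls was of this kind was not tested. The list count was reached by other splits too, so neither count is taken to exclude chance. For genes changed in the same direction in both lines, 1 of 100 splits reached the real 4769, with 0 in any other split drawn. Those splits mix preadipocyte and adipocyte arrays in 1 line or in both, which puts the difference between stages into the residual spread. The counts of 0 are therefore not taken to exclude chance.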

How the results depend on the processing

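Scaling to the hybridization controls and leaving out the brightest genes were tests chosen after the result was seen, as was leaving out arrays for the RNA controls. Counts of genes called stayed within 1.5 times their value in every comparison and alternative run. Of 527 results for named genes and 120 for lists, leaving aside single arrays, 17 gene results lost and 14 gained a call in at least 1 alternative, and 35 list results lost and 38 gained one, 34 of the losses with an estimated correlation and 38 of the gains with fry. These counts leave out 2 gene results and 2 list results that changed sign, given below. Of those, the 2 list results also gained a call with fry, and the gene result for Mt1 also lost its call. With an estimated correlation, 1 list passed for the difference between lines, 2 in adipocytes and 0 in preadipocytes, against 12, 6 and 12, with 14 in white differentiation against 16 and 14 in brown differentiation against 19. With fry these were 20, 21, 21, 22 and 21. At an adjusted p under 0.01, 6 lists passed in preadipocytes. With equal medians, 1405 genes were lower at least 2-fold in brown preadipocytes, against 858, and scaled to the hybridization controls 1531 genes rose in both lines, against 2299. The cause was not tested for these shifts.

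Some results changed sign. Where less specific probe sets were left out, another probe set stood for Dlk1 and for Mt1, a metallothionein. Dlk1 then had a difference between lines of 0.9452 (adjusted p = 0.0137, range 1.78e-07 to 0.322, against −1.36). Mt1 lost its call, with a difference between preadipocytes of 0.107 (adjusted p = 0.679, range 2.48e-09 to 0.679, against −0.91). Fry placed glucocorticoid response (adjusted p = 0.000134) and pyruvate dehydrogenase and citric acid cycle (adjusted p = 0.0172) on the other side of 0 for the difference between lines, in lists whose median and mean differed in sign. The cause was not tested.

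Leaving out 1 array gave 7963 to 8055 genes called in white differentiation, 7454 to 7762 in brown differentiation, 6560 to 6894 for the difference between lines, 7659 to 7764 in adipocytes and 6908 to 7196 in preadipocytes. With some array left out, 1 list result lost and 6 gained a call, and 5 gene results lost and 6 gained one. The rise of the beta-actin 3'/5' ratio was 0.851 in white cells (0.801 to 0.938 without 1 array) and 0.933 in brown cells (0.903 to 0.965).

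Replicate numbers gave no sign of pairing the samples. Deviations from the group means correlated within 0.03 of 0 between same-numbered arrays of different groups. Between differently numbered arrays these correlations ran from −0.042 to 0.039. Deviations from a mean of 3 arrays are weak ground, so pairing is not excluded. With the number as a block, 8147, 7701, 6563, 8105 and 7414 genes were called in the order above. A fit of only the arrays compared is the same fit for the difference between lines and was not run apart. Genes near the background limit these results, since signals below about 33 to 41 were not distinguished from the dimmest 40% of probe sets, and a pseudocount of 1 against 64 alters their log2 changes most.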

Other observations

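The genes in this part were tests chosen after the result was seen. They are genes of secreted factors outside the lists, Y-linked genes and Xist. Ccl9, a chemokine, stood at 12212 ± 609 in brown preadipocytes and 1074 ± 95.9 in white ones, and fell with differentiation in both, by log2 changes of −2.96 (SE 0.105, adjusted p = 6.14e-09) and −2.39 (SE 0.105, adjusted p = 1.63e-08). Ccl5, a chemokine that attracts T cells, fell in brown cells from 1421 ± 74.8 to 19.2 ± 18.3 (adjusted p = 5.23e-06), and its change in white cells did not pass (−1.07, adjusted p = 0.0882). Bmp4, a growth factor of early fat cell commitment, fell in brown cells from 814 ± 229 to 24.6 ± 21.0 (adjusted p = 2.51e-05) and had signals of 13.2 ± 12.1 and 18.1 ± 14.1 in white cells. Fgf7 fell in both lines, with log2 changes of −5.20 in brown and −2.26 in white cells.

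Igf2, an insulin-like growth factor, rose in white cells from 62.5 ± 15.5 to 548 ± 178 and fell in brown cells from 146 ± 13.5 to 22.3 ± 11.4. Igfbp4, which binds such factors, rose in white cells by 6.59 (SE 0.194) and fell in brown cells by 0.62 (SE 0.194, adjusted p = 0.0184). Bmper, a BMP regulator, changed by 2.34 and −1.79. Sema3g rose in both lines, by 7.39 in white and 2.56 in brown cells.

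The Y-linked genes Kdm5d and Uty had higher signals in the brown line. Kdm5d stood at 654 ± 109.8 and 539 ± 59.4 in brown preadipocytes and adipocytes and at 9.25 ± 8.59 and 8.12 ± 10.2 in white ones. Uty stood at 514 ± 56.6 and 598 ± 44.6 against 12.9 ± 12.8 and 12.8 ± 11.6. Xist, the transcript of the inactive X chromosome, lay between 34.0 ± 22.8 and 60.4 ± 18.5 in all 4 groups.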
